A study of Mus musculus with 14 samples.

How the data were processed

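The 14 libraries were poly(A) RNA of mouse placental spongiotrophoblast: IVF, WT SCNT and MKO SCNT placentas with 2 libraries each at E14.5 and at E19.5, and 1 IVF and 1 WT SCNT library at E9.5. Per the labels, the authors trimmed reads with Trim Galore, aligned them to mm9 with TopHat2 2.1.1 and made the deposited FPKM values with Cufflinks 2.2.1. Each file held 1 FPKM value for each of 22288 gene symbols, with no fragment counts and no coordinates. Total FPKM per library ran from 193247 to 343141. Because low FPKM values are multiples of the value of 1 fragment, the ratio of these values between libraries gave relative depth, from 0.606 to 1.73 of IVF E14.5 replicate 1. Without counts no counting interval was computed.

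The 12 libraries of E14.5 and E19.5 were fitted together with limma 3.58.1 in R 4.3.3 as 6 groups on log2(FPKM + 1), with a variance trend in the empirical Bayes step, 6 residual and 4.5 prior degrees of freedom. Fold changes are therefore those of FPKM plus 1. The 10975 genes at 1 FPKM or more in at least 2 of the 12 libraries were tested. Contrasts were WT SCNT against IVF, MKO SCNT against WT SCNT and MKO SCNT against IVF on each day, E19.5 against E14.5 in IVF, and the difference between the days of the first 2 effects. P values were two-sided and adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Replicate numbers were not taken to pair libraries. With 2 libraries per group, neither outlier tests nor other splits of the libraries were run. Standard errors are those of the moderated fit and SD is over 2 libraries.

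Gene lists were fixed before the data were examined, 28 in all: imprinted genes under H3K27me3, paternally expressed and maternally expressed imprinted genes, Y-linked genes, Xist, spongiotrophoblast, glycogen trophoblast, the prolactin family, giant cells, syncytiotrophoblast, fetal endothelium, stroma and pericytes, decidua, erythroid, natural killer, macrophage, neutrophil, yolk sac, amino acid transport, the amino acid response, cell cycle, glycogen metabolism, glycolysis, hypoxia and angiogenic genes, sterols and steroids, germline, immediate early and interferon genes. The 26 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, then with a correlation estimated per list and with fry, which asks whether the genes of a list move one way on balance. Lists of oocyte (18 genes), two_cell (12) and inner_cell_mass (8) transcripts were written after the highest E9.5 genes were seen and before the values of their members were.

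Genes were named by a rule set before the data were examined. In the 4 main comparisons it named Slc38a4, every tested member of the H3K27me3 list, and the 8 highest and 8 lowest log2 fold changes among genes past the test whose groups did not overlap and whose mean reached 2 FPKM, leaving out Y-linked genes, Xist, Tsix and unnamed gene models. Where none passed, it named the 4 lowest p values in each direction. In the other contrasts it named the 4 highest and 4 lowest. From each list it named up to 4 members with the lowest p values. At E9.5 it named the 8 highest and 8 lowest genes with a mean of at least 5 FPKM. Members and relatives outside the rule (C1qa, Prl2c2, Prl2c5, Prl3b1 and the genes said to move back) were chosen after their values were seen.

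For overlaps between comparisons that share libraries, 20 sets of unchanged groups were simulated with the estimated spread. For transcript lengths and processed pseudogene copies, symbols were matched to GENCODE M21 (20442 by symbol, 1200 through an older symbol, 646 not matched). Its genome build differs from that of the authors, so no coordinates are given. A copy was an alignment of at least 150 bases at 90% identity or more to 1 of 10244 processed pseudogene transcripts, found with BLAST+ 2.17.0+. A near-identical other gene was an alignment of the same kind to any annotated transcript of another symbol. The pipeline was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale in each main comparison: it recovered 73 to 84% and 97 to 99%, with 7 to 11 false calls, and called the moved list in each, along with 1 unmoved list in WT SCNT against IVF at E19.5 and 0 in the others. In these simulated data all groups shared 1 spread per gene, so the false calls do not cover groups of unequal spread. Figures and depth used Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9.

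Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter or a filter of 5 FPKM, median-ratio scaling, quantile normalization, only the compared groups in the fit, the replicate number as a block, no variance trend, microRNA and snoRNA genes kept, and each replicate left out in turn, where a lone library is assumed to vary like the other groups. Chosen after seeing the data were removal of a per-library trend with transcript length, a fit within the embryonic day, a fit without the MKO SCNT libraries of E19.5, genes with a pseudogene copy and ribosomal protein genes left out, and list tests without Prl3b1.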

Results

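Poly(A) RNA of the spongiotrophoblast was sequenced from mouse placentas in 14 libraries. The spongiotrophoblast is the hormone-producing layer between the labyrinth, where fetal and maternal blood exchange, and the maternal decidua. The control placentas came from in vitro fertilization (IVF). The cloned placentas came from somatic cell nuclear transfer (SCNT), in which the nucleus of a body cell replaces that of an oocyte, either from wild-type donors (WT SCNT) or with a maternal knockout of Slc38a4 (MKO SCNT). Slc38a4 encodes an amino acid transporter that placenta expresses mainly from the paternal copy, because H3K27me3 silences the maternal copy. Each of the 3 groups had 2 libraries at E14.5 and 2 at E19.5, and IVF and WT SCNT had 1 library each at E9.5. The series asks whether loss of Slc38a4 imprinting underlies the overgrowth of late SCNT placentas, so the comparisons asked how WT SCNT differed from IVF and what the maternal knockout changed.

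The values were FPKM (fragments per transcript length, scaled to the mapped fragments of a library) for 22288 gene symbols, of which 2178 were at 0 in all 14 libraries. The files gave no fragment counts, so absolute depth was unknown. Relative to replicate 1 of IVF at E14.5, the lowest nonzero FPKM values placed the fragments per library between 0.606 (IVF E19.5 replicate 1) and 1.73 (WT SCNT E9.5). Between 9589 and 10245 genes per library reached 1 FPKM. Across genes, replicates correlated with a Pearson's r from 0.957 in WT SCNT at E19.5 to 0.9896 in WT SCNT at E14.5. The labels did not say whether libraries came from separate placentas, so p-values measure only the spread between these samples. Ddx3y, a Y-linked gene, was above 1 FPKM in IVF replicate 2 of E14.5 and of E19.5. It was at 0 in every SCNT library of these days, so comparisons with IVF were not matched for sex.

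Slc38a4 transcripts were several times more abundant at E14.5 and E19.5 than at E9.5. At E14.5 the mean was higher in WT SCNT than in IVF, and with the maternal knockout it lay near that of IVF. At E19.5 WT SCNT and IVF lay closer together. The mean FPKM at E14.5 (± SD, n = 2) was 158.4 ± 7.84 in IVF, 232.7 ± 3.71 in WT SCNT and 146.5 ± 6.41 in MKO SCNT. At E19.5 it was 147.9 ± 11.4, 161.1 ± 21.4 and 118 ± 32.0 in the same order. None of these differences passed the test over all genes. WT SCNT against IVF stood at a log2 fold change of 0.55 ± 0.20 (SE) at E14.5 (adjusted p 0.247) and 0.12 ± 0.20 at E19.5 (adjusted p 0.688). MKO SCNT against WT SCNT stood at -0.67 ± 0.20 at E14.5 (adjusted p 1) and -0.47 ± 0.20 at E19.5 (adjusted p 0.181), and both libraries of MKO SCNT lay below both of WT SCNT on each day. For Slc38a4 alone, a gene named in advance, the unadjusted limma p of this comparison was 0.00649 at E14.5 and 0.0379 at E19.5. Under quantile normalization the E19.5 value of Slc38a4 reached -0.89 with an adjusted p of 0.0325, within a range up to 0.431 over the alternatives. Without MKO SCNT replicate 1 of E19.5 it stood at -0.19 and without replicate 2 at -0.74. The difference between the days was 0.20 (adjusted p 0.731).

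Genes listed as imprinted under H3K27me3 leaned higher in SCNT placenta. The values do not separate the parental copies, so whether each gene was silenced in this way in placenta was not tested. The list, fixed before the data were examined, had 16 members, 11 of them tested. At E14.5, 1 rose, 0 fell and 10 were not past the test, while 4 rose when adjusted over the list alone. That gene was Smoc1, which encodes a secreted matrix protein and rose by 0.99 ± 0.18 on the log2 scale (adjusted p 0.0383, 1.98-fold). Its call was lost when any single E14.5 library of WT SCNT or IVF was left out, and under median-ratio scaling or quantile normalization. At E19.5, 6 of the 11 rose, 0 fell and 5 were not past the test, with 7 up and 1 down when adjusted over the list alone. Gab1, an adaptor of growth factor receptors, rose by 1.54 ± 0.24 (adjusted p 0.00347, 2.90-fold). Sfmbt2, a polycomb-group protein gene, rose by 1.35 ± 0.28 (adjusted p 0.00961) and Sall1, a zinc finger factor, by 1.17 ± 0.27 (adjusted p 0.0162). Smoc1 (0.88), Phf17 (0.87) and Epas1 (0.69) also rose. Gab1 stayed past the test whichever 1 library was left out, whereas the other 5 lost their call without IVF replicate 1 or WT SCNT replicate 2 of E19.5. The camera test, which compares a list with all other genes, placed the list up at E14.5 (median 0.50, adjusted p 0.00114) and at E19.5 (median 0.69, adjusted p 0.0268). With an inter-gene correlation estimated from the data, these adjusted p values were 0.372 and 0.878.

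The maternal knockout left most of this list at its SCNT level at E14.5. The median in MKO SCNT against WT SCNT was -0.01 at E14.5 (adjusted p 0.811), with 0 of 11 genes past the limma test. At E19.5 the median was -0.23, with 10 of 11 genes below 0 and again 0 past the limma test. The camera adjusted p was 0.00231 (0.490 with the estimated correlation). The 11 genes include Slc38a4 itself (-0.47). Camera set the list against all other genes, and the median of all genes was 0.125 in this comparison. Against IVF, MKO SCNT had Gab1 (1.33), Sall1 (0.86) and Smoc1 (0.81) past the test at E19.5, the last 2 not in every fit that left out 1 library. Gab1 averaged 11.5 FPKM in IVF, 34.5 in WT SCNT and 30.2 in MKO SCNT on that day.

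**Figure D1:**
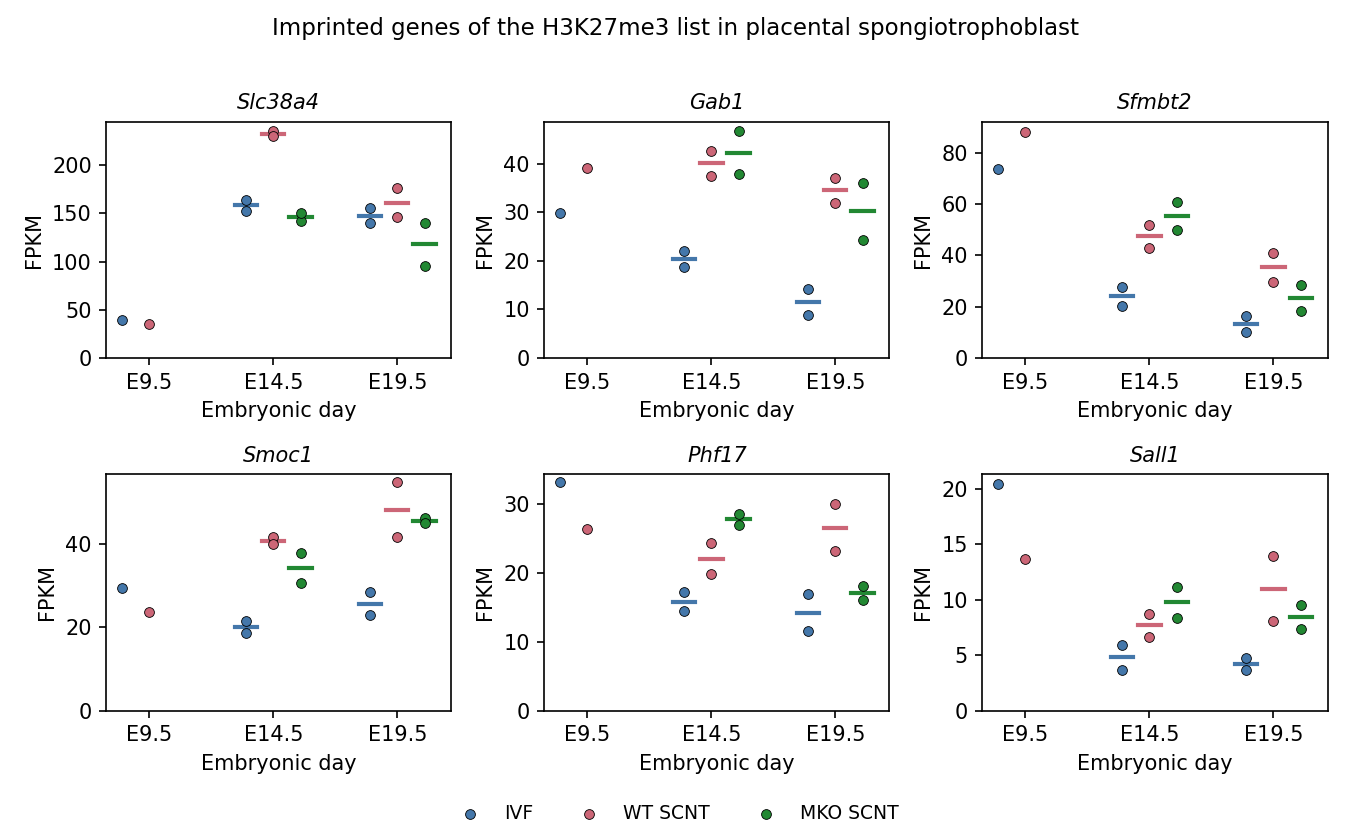
FPKM (y axis) of 6 genes of the H3K27me3 imprinted list by embryonic day (x axis), each point a library and each bar the mean of 2 libraries, with E9.5 libraries unreplicated. Slc38a4 lies at 230 or more FPKM in both WT SCNT libraries of E14.5 and below 165 in the IVF and MKO SCNT libraries of that day, whereas Gab1 and Smoc1 lie above every IVF library of E14.5 and E19.5 in both SCNT groups.

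At E14.5 the steepest falls in WT SCNT spongiotrophoblast among named genes past the test were in granzyme transcripts, which with perforin come from uterine natural killer cells. Embryonic globin transcripts of primitive red cells fell too, and so did the syncytin gene Synb and the transferrin receptor gene Tfrc, which mark the syncytiotrophoblast of the labyrinth. The decidua list leaned lower with no gene past the test. Pregnancy-specific glycoprotein genes of the spongiotrophoblast leaned lower without passing the test, and glycogen trophoblast genes leaned higher. Of these lists natural killer alone held with an inter-gene correlation estimated from the data. Amino acid transport and cell cycle lists were not called.

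Gzmf fell by 3.46 ± 0.31 on the log2 scale, 11-fold, from a mean of 64.4 to 4.99 FPKM, and Gzmc fell by 3.43 ± 0.22, from 22 to 1.18 FPKM. Gzmg (-3.24), Gzmd (-3.22) and Gzme (-2.62) followed. Cxcl14, a chemokine gene, fell by 2.87, from 11.7 to 0.699 FPKM. Hsd11b1, whose enzyme activates glucocorticoids, fell by 2.56 and Hbb-y, an embryonic globin gene, by 2.57, from 347 to 58.1 FPKM. Of the natural killer list 0 rose, 3 fell (Gzmc, Gzmb, Prf1) and 2 were not past the test, with 3 when adjusted over the list alone. Its median was -1.66, with an adjusted camera p of 1.22e-06, and it alone stayed past the threshold with the estimated correlation (p 0.0475). Of the erythroid list 0 rose, 4 fell (Hbb-y, Hba-x, Slc4a1, Hbb-bh1) and 3 were not past the test, against 6 adjusted over the list alone (median -1.79, adjusted p 6.64e-10, estimated-correlation p 0.127). The decidua list had 0 past the limma test and 1 adjusted over the list alone (median -1.40, adjusted p 0.000425, estimated-correlation p 0.372). In the syncytiotrophoblast list Tfrc (-2.42 ± 0.30) and Synb (-1.94 ± 0.32) fell, 3 when adjusted over the list alone, and 10 genes were not past the test (median -0.52, adjusted p 0.00114, estimated-correlation p 0.372).

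The spongiotrophoblast and glycogen trophoblast lists had medians on opposite sides of 0, with no test of the difference between them. None of the 26 spongiotrophoblast genes passed the limma test over all genes, while 1 rose and 8 fell adjusted over the list alone. The list median was -0.84 (adjusted p 1.34e-06, estimated-correlation p 0.372). Prl3a1 (-1.95), Psg17 (-1.13), Psg28 (-1.02) and Psg19 (-0.95) had its lowest p values and were not past the test. The glycogen trophoblast list, with 0 of 12 genes past the limma test and 2 up and 1 down adjusted over the list alone, had a median of 0.53 (adjusted p 0.00309, estimated-correlation p 0.395). Fetal endothelium (median -0.55, adjusted p 0.00118), stroma and pericytes (-0.57, 0.0283) and the amino acid response (-0.21, 0.00334) were also placed down, and their estimated-correlation p values were 0.376, 0.372 and 0.372. Among genes that rose, Pcsk6, a proprotein convertase gene, led at 1.69 ± 0.21 (3.22-fold), followed by the semaphorin receptor gene Plxnd1 at 1.63 ± 0.22, Apc2 at 1.61, Svep1 at 1.49, the dopamine receptor gene Drd4 at 1.47, Chrdl2, a BMP antagonist gene, at 1.39, the bile acid receptor gene Gpbar1 at 1.28 and Crispld2 at 1.17.

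In the limma test 83 of 10975 genes passed an adjusted p of 0.05 at E14.5, 26 higher and 57 lower in WT SCNT, and 1458 passed an unadjusted p of 0.05. The count was 8 without IVF replicate 1, 16 without WT SCNT replicate 1 and 23 without WT SCNT replicate 2. Of 25 named genes past the test, 5 (Gzmb, Gzmc, Gzmf, Gzmg, Prf1) stayed past it whichever 1 library was left out, and Gzmf and Gzmg lost their call with a pseudocount of 0.1. The other 20 lost their call without at least 1 library. The remaining lists were not placed apart from other genes: paternally expressed (median -0.18) and maternally expressed imprinted genes (-0.29), prolactin family (0.42), macrophage (0.09), neutrophil (-0.73), yolk sac (-0.20, with Trf down), amino acid transport (-0.07), cell cycle (0.06), glycogen metabolism (0.15), glycolysis (0.05), hypoxia and angiogenic genes (-0.14), sterols and steroids (0.07), germline genes (0.06 against a mean of -0.26), immediate early genes (-0.07) and interferon genes (-0.17). The giant cell list had a median of 0.26 but a mean of -0.01, and its test pointed down (adjusted p 0.828).

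At E19.5 WT SCNT placenta carried more of several trophoblast transcripts that were lower in late than in midgestation IVF placenta. Several glycogen trophoblast, amino acid transporter and prolactin genes rose, and so did both syncytin genes. Ceacam genes that were higher in late IVF placenta fell, and so did some pregnancy-specific glycoprotein genes. Peg3 and a few other paternally expressed genes rose along with Ascl2, a maternally expressed regulator of the spongiotrophoblast. Natural killer and erythroid lists, low in SCNT at E14.5, had medians near 0. In IVF several of their genes fell steeply from E14.5 to E19.5 (log2 fold change -4.275 for Gzmc and -7.895 for Hbb-y). This left those genes little room to lie lower in WT SCNT.

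Among named genes past the test Ceacam-ps1 showed the largest fall, by 5.79 ± 0.17 on the log2 scale, from 227.8 FPKM in IVF to 3.20 in WT SCNT. Ceacam15 fell by 3.90, from 227.7 to 14.4 FPKM, and the zinc transporter gene Slc30a3 fell by 3.82. Cryaa (-4.49), Ly6d (-4.25), Dcn (-4.03), Ctsk (-3.99) and S100a8 (-3.39) completed the 8 lowest, of which Cryaa, Dcn, Ctsk and S100a8 lost their call in at least 1 alternative. The highest of these named genes was Chrdl2 at 2.77 ± 0.24 (6.85-fold), from 2.44 to 22.4 FPKM. Both syncytin genes rose, Syna by 2.62 and Synb by 2.19, and so did the chemerin receptor gene Cmklr1 (2.54), Car2 (2.23, from 53.3 to 253 FPKM), Mmp15 (2.19), Clec12a (2.16) and Prl2b1 (2.12). In the glycogen trophoblast list 5 rose, 0 fell and 7 were not past the test, with 8 up adjusted over the list alone. Car2, Aldh1a3 (1.93), Pcdh12 (1.92) and Ncam1 (1.04) led it, and its median was 0.96 (adjusted p 0.0176, estimated-correlation p 0.878).

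Some amino acid transport genes rose in WT SCNT at E19.5. Of 22 tested, 8 rose, 0 fell and 14 were not past the test, with 10 adjusted over the list alone. The taurine transporter gene Slc6a6 (1.61), Slc43a2 (1.27), Slc7a1 (1.26) and Slc1a4 (0.97) had the lowest p values, and the first 3 lost their call without IVF replicate 1. The list median was 0.48 (adjusted p 0.0176, estimated-correlation p 0.767), and the call ended when the trend with transcript length was removed (adjusted p 0.284). The H3K27me3 list lost its call in the same way (0.129), as did the yolk sac list (0.309), in which Apoa1 (-1.66) and Trf (-1.50) fell. The yolk sac list stood at a median of -0.66 (adjusted p 0.0443, estimated-correlation p 0.767, and 0.145 under quantile normalization). In the spongiotrophoblast list 4 rose (Ascl2 by 2.00 and Flt1 by 0.94 among them), 6 fell (Psg17 by 1.55 and Psg22 by 1.06 among them) and 16 were not past the test. Its median was -0.53 (adjusted p 0.0819), and under quantile normalization its test pointed up (adjusted p 0.976). The prolactin list split too, with 7 up (Prl4a1 1.68, Prl7a2 1.49), 2 down (Prl5a1 -3.00) and a median of 0.52 (adjusted p 0.518). Of paternally expressed imprinted genes 4 rose and 0 fell: Peg3 (1.39), Peg13 (0.66), Impact (0.61) and Inpp5f (0.59). In the maternally expressed list Ascl2 and Slc22a3 rose and Dcn and Tnfrsf23 fell, with a median of 0.11, a mean of -0.21 and a test pointing down (adjusted p 0.829). The cell cycle list stood at a median of 0.11, with 0 of 22 genes past the limma test.

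In the limma test 2470 genes passed at E19.5, 1576 (63.8%) higher and 894 lower, and 4244 passed an unadjusted p of 0.05. Median-ratio scaling gave 1393 higher and 1386 lower, and quantile normalization 1485 and 1249, so the share that was higher depended on the scaling. Without IVF replicate 1 of E19.5 the count was 265, and without WT SCNT replicate 2 it was 1093. Of 77 named genes past the test, 23 stayed past it whichever library was left out, and those given here were Ascl2, Car2, Ceacam-ps1, Ceacam15, Chrdl2, Clec12a, Cmklr1, Gab1, Ly6d, Mmp15, Pcdh12, Prl2b1, Prl5a1, Slc1a4, Slc30a3, Syna, Synb and Trf. The other 54 lost their call without at least 1 library.

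**Figure D2:**
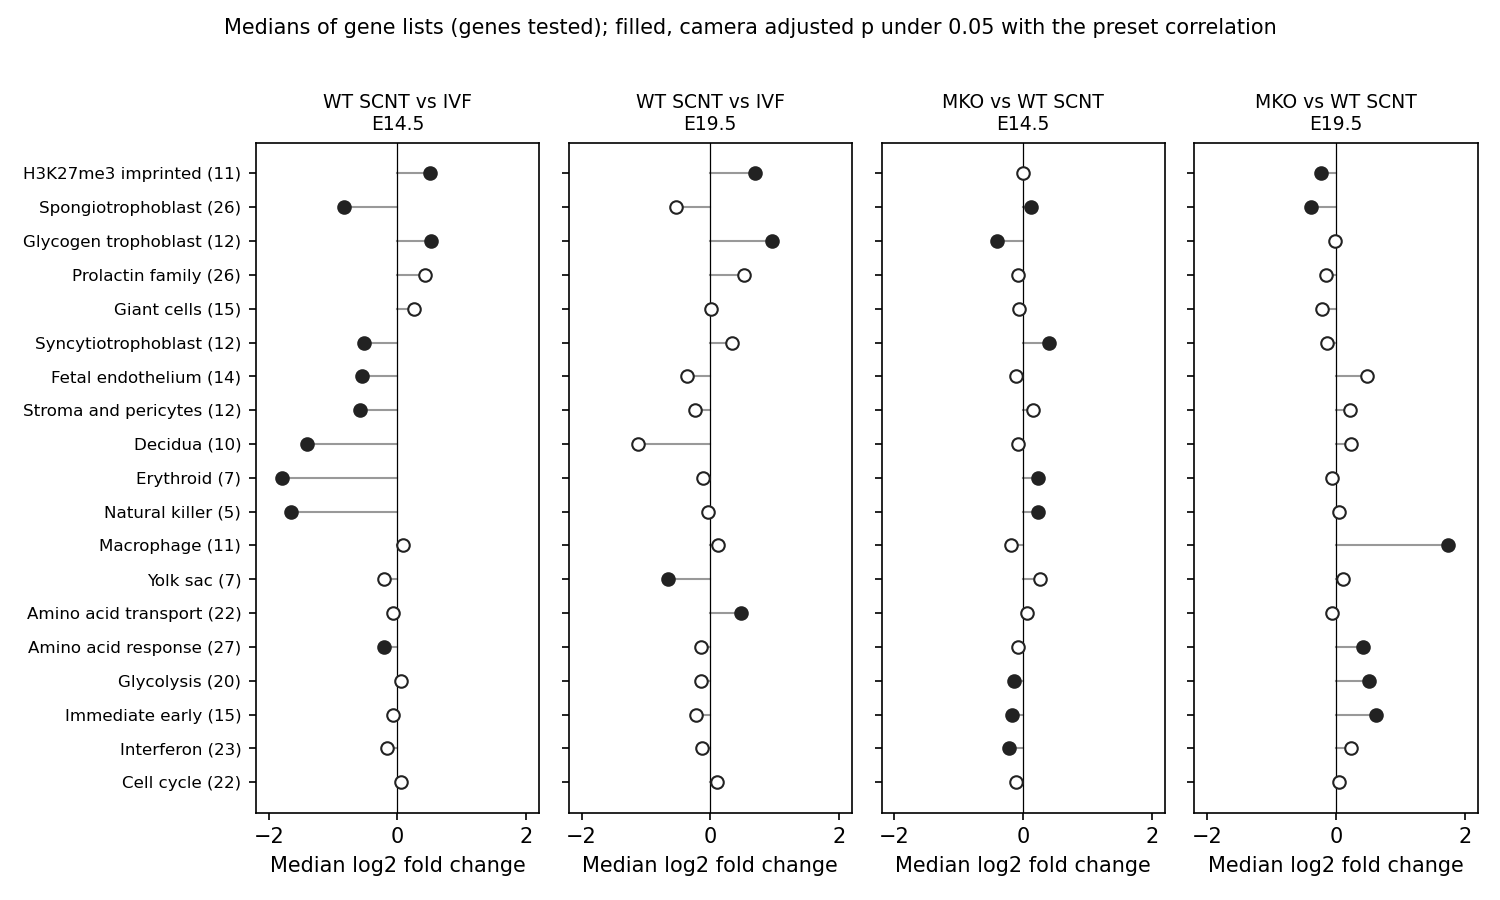
Median log2 fold change (x axis) of the tested genes of 19 lists (y axis, number of tested genes in brackets) in the 4 main comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation. In WT SCNT against IVF the H3K27me3 imprinted list lies at 0.50 and 0.69 on the 2 days, and the erythroid and natural killer lists lie at -1.79 and -1.66 at E14.5 but at -0.11 and -0.04 at E19.5.

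Some SCNT effects differed between the days by a direct test. Synb was lower than in IVF at E14.5 and higher at E19.5, and Ceacam-ps1 and Ceacam15 lay further below IVF at E19.5 than at E14.5. The difference between the days passed the limma test for 66 genes, 22 positive and 44 negative, with 1415 at an unadjusted p of 0.05. The count was 31 without IVF E14.5 replicate 1, 28 without IVF E14.5 replicate 2, 15 without IVF E19.5 replicate 1, 24 without IVF E19.5 replicate 2, 34 without WT SCNT E14.5 replicate 1, 20 without WT SCNT E14.5 replicate 2 and 157 without WT SCNT E19.5 replicate 1. The 2 effects also shared genes: 45 of the 83 genes called at E14.5 were called in the same direction at E19.5, 18 up against 3.73 by chance and 27 down against 4.64. No library entered both effects, and across genes they correlated at a Pearson's r of 0.589, genes being no independent replicates.

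At E14.5 the knockout clones had a profile close to that of WT SCNT. No gene passed the test, although the syncytiotrophoblast and natural killer lists leaned back up and the glycogen trophoblast list back down, each against its direction in WT SCNT against IVF. Interferon, glycolysis and hypoxia lists leaned down. None of these list calls held with an inter-gene correlation estimated from the data.

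The limma fit pooled the variance of each gene over all 6 groups. Over all genes the SD between replicates (log2) was 0.18 in WT SCNT and 0.231 in MKO SCNT at E14.5, against 0.359 and 0.318 at E19.5. The test was therefore stricter than the spread of these groups at E14.5 and less strict at E19.5. With limma 0 of 10975 genes passed in MKO SCNT against WT SCNT at E14.5, and 237 passed an unadjusted p of 0.05. Without MKO SCNT replicate 1 the count was 2. The lowest p values, none past the test and all at an adjusted p of 1, belonged to Synb (1.40 ± 0.32), Gzmc (0.76), Prr12 (0.58) and Adssl1 (0.49) among positive values and to Snhg12 (-0.70), the sterol gene Nsdhl (-0.62), Snhg3 (-0.58) and Rps15a-ps4 (-0.49) among negative ones. Adjusted over the list alone, 1 syncytiotrophoblast and 2 natural killer genes passed. The camera test placed the syncytiotrophoblast (median 0.41, adjusted p 2.31e-05), natural killer (0.23, 0.000125), spongiotrophoblast (0.12, 0.0141), erythroid (0.24, 0.0190) and paternally expressed imprinted lists (0.18, 0.0270) up. It placed the interferon (-0.22, 2.31e-05), glycolysis (-0.14, 0.00123), hypoxia (-0.21, 0.00215), glycogen trophoblast (-0.41, 0.00299) and immediate early lists (-0.18, 0.0139) down. With the estimated correlation their adjusted p values ran from 0.132 for natural killer to 0.665 for spongiotrophoblast, and under quantile normalization the erythroid (0.0637) and paternal (0.138) calls ended. Both comparisons used the same WT SCNT libraries, which alone pushes them in opposite directions: across genes r was -0.223, against -0.405 in simulated unchanged groups, and the covariance was 1.33 times the simulated one. Prl3b1, a placental lactogen gene, was listed at 0 in MKO SCNT replicate 2, although every other library of E14.5 and E19.5 held at least 8303 FPKM. A listed 0 cannot be told from a value that was not computed, and leaving out Prl3b1 changed no list call.

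At E19.5 several macrophage and glycolysis genes and most ribosomal protein genes rose in the knockout libraries against WT SCNT. Both of these libraries also stood apart in how the FPKM value of 1 fragment varied with transcript length, by 0.068 and 0.0752 (log2, short minus long transcripts) against -0.013 to 0.009 in the others. Complement C1q genes rose along with lysosomal and immune receptor adaptor genes. The pregnancy-specific glycoprotein genes Psg22 and Psg18 fell. The amino acid transport list was not called, while genes induced by amino acid shortage leaned up with 2 of 27 past the test and an estimated-correlation p of 0.490.

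Among named genes past the test Prl2c4, a proliferin gene, showed the largest change, a rise of 7.34 ± 0.73, from 1.36 FPKM in WT SCNT to 319.5 in MKO SCNT, with 2.03 in IVF. Its close relatives Prl2c3 (-1.79), Prl2c1 (-1.03), Prl2c5 (-0.41) and Prl2c2 (-0.37) were all below 0 and not past the test. Prl2c3 averaged 940.1 FPKM in WT SCNT and 302.8 in MKO SCNT. Rpl38 rose by 3.75, from 11.4 to 165.5 FPKM, and Rps8 (3.54), Rps28 (3.45), Rpl28 (3.36), Rpl31-ps12 (3.26), Gapdh (3.24 ± 0.20, from 15.9 to 158 FPKM) and Hist2h2ac (3.12) completed the 8 highest. The ribosomal protein genes were examined as a set only after these values were seen: 64 of 79 rose and 1 fell, with a median of 1.63. Their median was 1.47 under median-ratio scaling and 1.36 under quantile normalization, and it was -0.35 in the same comparison at E14.5. At E19.5 the set was lower in WT SCNT than in IVF (median -0.53, with 0 genes up and 31 down past the test), and in MKO SCNT against IVF its median was 1.13, with 54 up and 4 down. The lowest values among named genes past the test were those of Bex2 (-2.72, from 27.8 to 3.38 FPKM), Csl (-2.52), the class I histocompatibility genes H2-Q10 (-2.40) and H2-K2 (-2.17), Bex4 (-2.09), Hist1h2bm (-1.92), Fndc3c1 (-1.88) and Hist1h2bn (-1.84). Each of the 8 highest and 8 lowest stayed past the test in every alternative that tested it. The fit without ribosomal protein genes and genes with a pseudogene copy did not test Rpl38, Rps8, Rps28 and Rpl28. Nor did it test any other of these genes that has a copy or was not matched to an annotated transcript. For these genes the alternatives therefore do not address reads shared with copies.

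In the macrophage list 6 rose, 0 fell and 5 were not past the test, with 8 adjusted over the list alone. C1qb (2.47), Ctss (2.19), Tyrobp (1.94) and Laptm5 (1.67) led it and C1qa averaged 68.6 FPKM against 9.42. C1qb and Psmb9, an interferon gene, lost their call without MKO SCNT replicate 1. The list median was 1.74 (adjusted p 0.000103, estimated-correlation p 0.490). In the glycolysis list 7 rose, 0 fell and 13 were not past the test, with 12 adjusted over the list alone. Gapdh, Eno1 (1.89), Pgk1 (1.52) and Pgam1 (1.27) led it, with a median of 0.52 (adjusted p 5.20e-05, estimated-correlation p 0.490). These rises came from the same libraries as those of the ribosomal protein genes. Whether reads shared with pseudogene copies or library preparation gave part of them was not tested for this list. In the spongiotrophoblast list Psg22 (-1.36) and Psg18 (-1.21) fell, 0 rose, and 24 were not past the test, with 2 adjusted over the list alone and 23 of 26 below 0 (median -0.38, adjusted p 1.65e-06, estimated-correlation p 0.490). Psg18 lost its call without MKO SCNT replicate 1 or WT SCNT replicate 1, and Psg22 in the fit of the compared groups alone. The amino acid response list was placed up (median 0.42, adjusted p 0.00813, estimated-correlation p 0.490), with 2 genes that rose, Slc7a11 (1.01) and Gars (0.56), 25 not past the test and 3 adjusted over the list alone. The immediate early list was up as well (median 0.63, adjusted p 0.0309, estimated-correlation p 0.490), with Ier2, Jun and Klf4 risen and 6 adjusted over the list alone, and its call ended under quantile normalization (adjusted p 0.177). In the interferon list 5 of 23 genes rose, among them Psmb8 (1.30), Psmb9 (1.19), Irf7 (0.80) and Oas1a (0.73), and the list itself was not called (median 0.24, adjusted p 0.0757). The amino acid transport list stood at -0.07 (adjusted p 0.123). The stroma and decidua lists had positive medians of 0.22 and 0.24 but tests pointing down (adjusted p 0.913 and 0.626).

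In the limma test 839 genes passed at E19.5, 781 (93.1%) higher and 58 lower, around a median of all genes of 0.125, with 2600 at an unadjusted p of 0.05. Median-ratio scaling left 532 genes, 441 higher and 91 lower, and quantile normalization 507, with 394 higher and 113 lower. Without MKO SCNT replicate 1 the count was 326, without MKO SCNT replicate 2 442, without WT SCNT replicate 2 551 and without WT SCNT replicate 1 1358. Of 42 named genes past the test, 27 stayed past it whichever library was left out, and Gars, Ier2, Irf7, Jun, Klf4 and Oas1a were among the 15 that did not. The effect of the knockout differed between the days for 385 genes, 364 of them positive, around a median of all genes of 0.157, and median-ratio scaling and quantile normalization gave 251 and 238. That count was 220 without WT SCNT E14.5 replicate 1, 158 without WT SCNT E14.5 replicate 2, 193 without MKO SCNT E14.5 replicate 2, 217 and 237 without MKO SCNT E19.5 replicates 1 and 2, and 580 without WT SCNT E19.5 replicate 1.

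At E19.5, 205 of the 2470 genes altered in WT SCNT moved back past the limma test with the knockout, most of them lower in WT SCNT, and 1959 of the 2470 had the opposite sign. Of these 205, 9 were high in WT SCNT and fell with the knockout, against 8.33 expected by chance, and 196 were low and rose, against 63.6. These expected counts take the 2 comparisons as independent, which they are not, since both used the same WT SCNT libraries. At E14.5 limma called 0 genes in MKO SCNT against WT SCNT (237 at an unadjusted p of 0.05), so a move back could not be counted, and 70 of the 83 genes had the opposite sign. The late IVF genes Ceacam-ps1 (2.40), Ceacam15 (1.43) and Slc30a3 (1.25) were among those that rose, and each stayed below IVF past the test. Against IVF, 139 of the 205 were not called, 14 were still called in the WT SCNT direction and 52 were called on the other side, among them Rpl38 and Rps8. Of the 205, 122 were neither ribosomal protein genes nor genes with a pseudogene copy, and the rises came from the MKO SCNT libraries whose fragment value varied with transcript length. For these shared libraries, unchanged groups in simulation gave an r of -0.642 across genes where the data gave -0.478, while the covariance in the data was 2.43 times the simulated one. The simulated groups shared an average of 0.3 calls in any direction. With no changed genes in the simulation few calls were possible, so that number does not show how many of the 205 the shared libraries gave.

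WT SCNT and MKO SCNT shared part of their differences from IVF. Of the 83 genes called in WT SCNT against IVF at E14.5, 50 were called in the same direction in MKO SCNT against IVF and 0 in the opposite one by limma. At E19.5, 1143 of 2470 were called in the same direction, 52 in the opposite one and 1275 were not called. Both comparisons used the same IVF libraries, which alone gave an r across genes of 0.51 at E14.5 and 0.281 at E19.5 in simulated unchanged groups, where the data gave 0.872 and 0.679 (covariance 7.7 and 11.8 times the simulated one). In MKO SCNT against IVF 63 genes passed at E14.5 (13 higher, 50 lower, 1694 at an unadjusted p of 0.05), with Plxnd1 (1.95) and Pcsk6 (1.63) highest and Cryab (-3.90) and S100a8 (-3.43) lowest among the named genes past the test. The count at E14.5 was 2 without IVF replicate 1, 29 without MKO SCNT replicate 1 and 11 without MKO SCNT replicate 2, and the 4 genes given each lost their call without at least 1 library. At E19.5, 2386 passed (1969 higher, 417 lower, 4022 at an unadjusted p of 0.05) around a median of all genes of 0.213, and median-ratio scaling gave 947 higher and 773 lower. That count was 1132 without IVF replicate 1, 1291 without IVF replicate 2 and 897 without MKO SCNT replicate 2. Prl2c4 (7.11), Apoe (3.36) and C1qa (3.31) were the highest named genes past the test and Ly6d (-3.63), Cryaa (-3.58) and Ceacam-ps1 (-3.38) the lowest, of which Cryaa alone lost its call without 1 library. At E19.5 the spongiotrophoblast list stood at -1.05 with 3 genes up and 12 down (adjusted p 2.51e-10), the glycogen trophoblast list at 1.32 with 6 up (0.0179), the macrophage list at 2.14 with 7 up (0.0179) and the decidua list at -0.77 (0.0179), and with the estimated correlation each of these 4 p values was 0.758.

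IVF placenta changed widely between E14.5 and E19.5. In IVF 16 of 22 cell cycle, 11 of 17 sterol and 10 of 22 amino acid transport genes fell, as did both syncytins and several glycogen trophoblast, granzyme and embryonic globin genes. Prl3a1, Doxl2 and Ceacam-ps1 rose steeply, while of the spongiotrophoblast list 8 rose, 2 fell and 16 were not past the test (median 0.41, adjusted p 0.0540). Of the interferon list 11 of 23 genes rose and 1 fell, and of the immediate early list 6 of 15 rose and 0 fell.

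Doxl2, a diamine oxidase-like gene, rose by 9.30 on the log2 scale, Ceacam-ps1 by 7.48, Prl3a1 by 6.80 and Slc30a3 by 5.93. The lowest values among named genes past the test were those of Hbb-y (-7.89), Hba-x (-6.03), Ceacam9 (-5.09) and Gzmf (-5.03). Of 22 cell cycle genes 0 rose, 16 fell and 6 were not past the test (median -0.75, adjusted p 0.000316, estimated-correlation p 0.687). Of 17 sterol and steroid genes 1 rose and 11 fell, among them Dhcr24 (-2.42), Ldlr (-2.36) and Sqle (-1.80), with a median of -0.73 (adjusted p 0.00108, estimated-correlation p 0.509). Of 22 amino acid transport genes 1 rose and 10 fell, Slc7a2 by 1.53 among them (median -0.48, adjusted p 0.0126, estimated-correlation p 0.454). Glycogen trophoblast genes fell in 8 of 12 cases, Car2 by 3.17 and Prl6a1 by 3.10 (median -1.3, adjusted p 0.00522), and syncytiotrophoblast genes in 6 of 12, Syna by 2.90 and Synb by 2.89 (median -0.76, adjusted p 0.0130). The estimated-correlation p of both lists was 0.549. Erythroid (-1.89), natural killer (-2.12) and glycogen metabolism lists (-0.56) were also placed down, at adjusted p values of 0.000206, 0.000316 and 0.0135 and estimated-correlation p values of 0.304, 0.161 and 0.549. Interferon (0.61, 0.000716), immediate early (0.32, 0.0148) and yolk sac lists (1.23, 0.0130) were placed up, with estimated-correlation p values of 0.304, 0.509 and 0.304, and Gbp2 (1.70), Ier3 (2.68), Junb (2.29) and Apoa1 (4.62) rose.

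In the limma test 3097 genes passed in this comparison, 1317 higher and 1780 lower, with 4594 at an unadjusted p of 0.05. Median-ratio scaling gave 1719 higher and 1599 lower, and quantile normalization 1613 and 1795. Without IVF E14.5 replicate 2 the count was 1089 and without IVF E19.5 replicate 1 it was 1187. Of 90 named genes past the test, 62 stayed past it in every alternative, those given here included. Of the 3097 genes, 2693 (87%) had the opposite sign in WT SCNT against IVF at E19.5. Across all tested genes the 2 comparisons correlated at a Pearson's r of -0.614, against -0.354 in simulated unchanged groups that shared the IVF libraries of E19.5 in the same way.

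**Figure D3:**
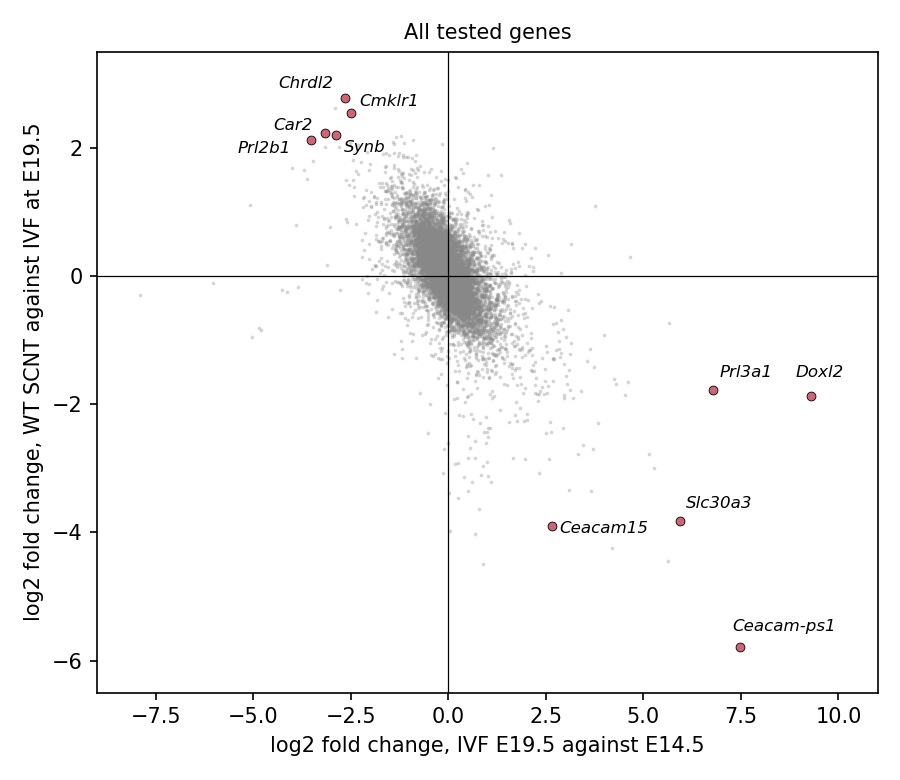
Log2 fold change in WT SCNT against IVF at E19.5 (y axis) against that in IVF from E14.5 to E19.5 (x axis) for 10975 tested genes, each point a gene and 10 named genes in colour. Ceacam-ps1 lies at 7.48 on the x axis and -5.79 on the y axis, and Prl2b1 at -3.51 and 2.12.

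At E9.5 the libraries were unreplicated and no test between groups was run, so the values describe 1 IVF and 1 WT SCNT library, and percentiles against random lists measure only the spread over genes between them. The WT SCNT library held oocyte and early embryo transcripts that were far lower in the other libraries. Omt2b, a transcript of oocytes, was at 342 FPKM against 0.0349, and Omt2a at 190.6 against a listed 0. Trim43b (143.5), BC052688 (124.5), Alppl2 (117.4), Oog3 (100.7), Trim43c (86.2) and Dppa3 (81.9 FPKM) completed the 8 highest, and Dppa3 reached 1.72 FPKM elsewhere, in IVF at E19.5. In the other direction natural killer, macrophage and giant cell transcripts were lower in WT SCNT. Hbb-b1 was at 4.24 FPKM against 47.1, and Gzmf at 25.5 against 129.6. Rsc1a1, S100a9, Spp1, Prf1, Gzmg and Thy1 completed the 8 lowest.

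Among 10740 genes at 1 FPKM or more in either E9.5 library, 994 were 2-fold or more higher in WT SCNT and 187 lower, around a median of all genes of -0.35. The libraries correlated at a Pearson's r of 0.8697 across genes. Against 10000 random lists of the same size, the cell cycle list (median 0.03, percentile 100) and the germline list (1.17, 99.6) lay at the top, followed by the amino acid response (98.9), spongiotrophoblast (98.1) and hypoxia lists (97.6). Natural killer (-1.45), neutrophil (-1.39), macrophage (-1.35), giant cell (-1.08), prolactin (-0.83), immediate early (-0.69), stroma (-0.67) and yolk sac lists (-0.64) lay at percentile 0. The H3K27me3 list stood at -0.30 (percentile 85.2), and Slc38a4 at 35.1 FPKM in WT SCNT against 39.3 in IVF.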

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

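Among the tests here, those of pseudogene copies and of library preparation for ribosomal protein genes, and those of shared libraries, of transcript length, of the E14.5 effect and of cell cycle, erythroid and natural killer genes for the time course, were chosen after the result was seen.

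The effect of WT SCNT against IVF differed between E19.5 and E14.5 in 66 genes by a direct test of the difference, on which the following values rest. Leaving out 1 library gave 15 (IVF E19.5 replicate 1) to 34 genes (WT SCNT E14.5 replicate 1) for 6 of the 8 libraries involved, and 157 without WT SCNT E19.5 replicate 1. The log2 difference was 4.13 for Synb, 3.41 for Syna, 3.20 for Gzmc and 2.96 for the sulfate transporter gene Slc13a4. It was -3.42 for Ceacam15, -3.74 for Slc30a3, -3.93 for Ly6d and -5.46 for Ceacam-ps1. Synb, Ceacam15, Slc30a3 and Ceacam-ps1 stayed past the test in every alternative that gave a value. By list, the median difference was 0.82 for syncytiotrophoblast, 1.97 for erythroid, 1.62 for natural killer, 0.53 for amino acid transport and -0.28 for glycolysis genes. With the estimated correlation their adjusted p values were 0.585, 0.385, 0.0808, 0.231 and 0.793. Several natural killer and erythroid genes fell steeply over time in IVF (Gzmc -4.275, Hbb-y -7.895). Their low values at E19.5 limit how far WT SCNT could lie below IVF on that day.

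The effect of MKO SCNT against WT SCNT differed between the days in 385 genes. The log2 difference was 6.77 for Prl2c4, 4.41 for Rpl38, 4.09 for Rps28 and 4.02 for Rps8, and it was -2.06 for Psg20, -2.13 for H2-Q10, -2.50 for Bex2 and -2.63 for Csl. All of these but Prl2c4 and Psg20 stayed past the test in every alternative that gave a value. By list, the median difference was -0.20 for H3K27me3 imprinted, -0.12 for paternally expressed imprinted, -0.56 for spongiotrophoblast, -0.46 for syncytiotrophoblast, 1.54 for macrophage, 0.48 for amino acid response, 0.66 for glycolysis, 0.71 for immediate early and 0.50 for interferon genes, around a median of all genes of 0.157. With the estimated correlation their adjusted p values lay between 0.435 and 0.480. Without genes that have a pseudogene copy and ribosomal protein genes, a fit that did not test Rpl38, Rps28 and Rps8, the count was 47. It was 158 without WT SCNT E14.5 replicate 2, 193 without MKO SCNT E14.5 replicate 2, 217 and 237 without MKO SCNT E19.5 replicates 1 and 2, 220 without WT SCNT E14.5 replicate 1 and 580 without WT SCNT E19.5 replicate 1.

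Ribosomal protein and housekeeping transcripts were higher in both MKO SCNT libraries of E19.5. Ribosomal protein genes made up 4.22% and 3.87% of the FPKM there, against 1.36% to 2.03% in the other libraries of E14.5 and E19.5 and 3.75% and 3.16% at E9.5. A trend with the length of the longest annotated transcript is argued against as the whole cause: after its removal their median log2 change was still 1.18 (quartiles 0.606 to 1.85). An effect tied to shorter transcripts of the same genes is not covered by this test. Reads shared with pseudogene copies stay open, by a reading changed after the values were seen: 483 other genes with 3 or more copies lay only 0.0727 above matched genes without one (bootstrap 95% interval 0.0412 to 0.115) and the 3 ribosomal protein genes without a copy had a median of 1.23, but 20.7% of the 483 were called higher against 4.83% of matched genes. A difference in library preparation stays open too and cannot be told apart from the knockout at E19.5: the value of 1 fragment differed between short and long transcripts by 0.068 and 0.0752 in these libraries against -0.013 to 0.009 in the others, so effective lengths in the quantification may have differed, and an effect of the knockout itself is untested.

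In the other direction, the profile of WT SCNT at E19.5 ran against the change of IVF placenta from E14.5 to E19.5. The shared IVF libraries of E19.5 are argued against as the whole cause, since the covariance across genes was 14.1 times that of simulated unchanged groups, and so is transcript length, since r was -0.592 after removal of its trend. For part of the genes the values at E19.5 are those that a profile of an earlier stage in WT SCNT placenta would give. The change of MKO SCNT from E14.5 to E19.5 shares no library with the WT SCNT effect. It correlated with that effect at -0.358 over 9044 genes (Spearman -0.35). With the WT SCNT effect of E14.5 it correlated at -0.196 (-0.265 over all genes, against -0.451 at E19.5). Of genes called both over time in IVF and in WT SCNT against IVF at E14.5, 33 shared a direction and 18 did not. Of the 33, 27 fell in both, against 9.24 expected by chance. Both comparisons used the IVF libraries of E14.5, which alone pushes them the same way. Across all genes their r was -0.133, against 0.546 in simulated unchanged groups. An earlier stage at E14.5 thus stays open. For cell cycle, erythroid and natural killer genes the test could not decide. The 25 that fell over time in IVF had a median of 0.0994 in WT SCNT against IVF at E19.5. The bootstrap 95% interval, which takes genes as independent, was 0.0316 to 0.187. It lay under the bound of 0.2, chosen after the result was seen, but wholly on the positive side, where an earlier stage would place it. Members went both ways, with Cdt1 at 0.28, Hbb-y at -0.30 and Gzmc at -0.22. Hbb-y and Gzmc had little room to lie below IVF, having changed by -7.895 and -4.275 over time in IVF. Gzmc was also low in WT SCNT at E14.5, which left it little room above IVF. Hbb-y lay much less far below IVF at E14.5 than it fell over time in IVF. It therefore had room to lie above IVF at E19.5 and did not. WT SCNT followed the IVF time course with a slope of 0.562 and MKO SCNT with 0.756, and whether slower maturation or a different mix of cells gives this profile was not tested.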

How the results depend on the processing

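The fits with the length trend removed, within the embryonic day, without MKO SCNT of E19.5 and without genes that have a copy were chosen after the data were seen. No call reversed: of the other values for named genes 6470 kept their side of the threshold, 942 lost and 19 gained a call. Signs short of a call did turn: Slc38a4 in WT SCNT against IVF at E19.5 without WT SCNT replicate 1, and the spongiotrophoblast list there under quantile normalization. Median-ratio scaling turned the IVF time balance to 1719 higher and 1599 lower. For counts that moved, the cause was not tested. Fits of fewer groups take the variance from those groups alone, and the SD between replicates (log2) ran from 0.18 (WT SCNT E14.5) to 0.359 (WT SCNT E19.5). In order WT SCNT against IVF, MKO SCNT against WT SCNT and MKO SCNT against IVF, a fit of the compared groups gave 368 (E14.5) and 736 (E19.5), 237 (E19.5), and 274 (E14.5). A fit within the day gave 261 and 988, 346 (E19.5), and 199 and 1303. Length removal gave 382 for MKO SCNT against WT SCNT at E19.5, 39 for MKO SCNT against IVF at E14.5 and 168 for the knockout difference between days. Leaving out genes with a copy, which tests fewer genes, gave 292 and, for that difference, 47. Median-ratio scaling gave 532 and 251 there, and quantile normalization 507 and 238. Quantile normalization also took Slc38a4 past the test in MKO SCNT against WT SCNT at E19.5 (-0.89). A pseudocount of 0.1 gave 52 in WT SCNT against IVF at E14.5. The SCNT difference between days was 24 with a pseudocount of 0.1, 109 with 5 and 31 with a filter of 5 FPKM. No filter gave 1 gene in MKO SCNT against WT SCNT at E14.5.

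Leaving out 1 library gave 8 to 101 genes (E14.5) and 265 to 2733 (E19.5) in WT SCNT against IVF, 0 to 2 and 326 to 1358 in MKO SCNT against WT SCNT, 2 to 68 and 897 to 1623 in MKO SCNT against IVF, 1089 to 2417 over time in IVF, and 15 to 157 and 158 to 580 for the differences between days. Slc38a4 ran from 0.50 to 0.60 and -0.02 to 0.25 in WT SCNT against IVF, and from -0.71 to -0.62 and -0.74 to -0.19 in MKO SCNT against WT SCNT.

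Of the lists called, the estimated correlation left 1 in WT SCNT against IVF at E14.5 and 0 in the other 8 contrasts. With fry 2 were called in WT SCNT against IVF on each day, 0 in MKO SCNT against WT SCNT at E14.5, 2 in MKO SCNT against IVF at E14.5, and 2 and 4 for the differences between days. Length removal left 1 in WT SCNT against IVF at E19.5. At an unadjusted p of 0.05 with a 1.5-fold change, 24 genes moved back at E14.5 and 384 at E19.5. At E9.5, 16 lists lay outside the central range of random lists in each of 3 settings. With a pseudocount of 0.1 and with median-ratio scaling, 15 of them were the same as in the reported setting.

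With the replicate number as a block the counts for WT SCNT against IVF were 101 and 2522, for MKO SCNT against WT SCNT 0 and 816. Deviations of replicate 1 correlated between groups from -0.458 to 0.309, 9 of 15 pairs positive. Keeping microRNA and snoRNA genes moved nothing, as 0 symbols matched. Unknown depth left genes near 0 without a limit.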

Other observations

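Of the 3 tests of the E9.5 library, that of multi-copy families was chosen after the result was seen and the other 2 had bounds set before their values were read, on lists and genes chosen after the highest genes were seen, and Dcn, Xist and the Y-linked genes per library were chosen after their values were seen.

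Sterol genes moved both ways in late WT SCNT placenta. At E19.5 in WT SCNT against IVF 3 of 17 rose and 2 fell, with a median of 0.28 (adjusted p 0.335, estimated-correlation p 0.878), and in IVF 11 of them fell from E14.5 to E19.5. Glycogen metabolism genes stood at a median of 0.32 at E19.5 in WT SCNT against IVF, with 3 of 16 risen and 0 fallen (adjusted p 0.287). Decorin, a matrix proteoglycan gene of stroma (Dcn), varied between libraries of 1 group: 36.2 and 0.499 FPKM in MKO SCNT at E19.5, and 0.08 and 8.85 in WT SCNT, against 49.0 and 55.7 in IVF.

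Ddx3y, a Y-linked gene, was read in IVF replicate 2 at E14.5 (1.74 FPKM) and at E19.5 (1.30) and in IVF at E9.5 (0.67), and it was at 0 in the SCNT libraries of E14.5 and E19.5. In the WT SCNT library of E9.5 it was at 0.0295 FPKM, but Uty was at 0.361 and Eif2s3y at 0.385, against 0.0612 and 0.484 in IVF at E9.5 and 0 in the later SCNT libraries. Xist was at 9.19 and 2.1 FPKM in IVF at E14.5 and at 6.20 and 0.362 in IVF at E19.5. Tested genes of these lists stood at -0.75 (Ddx3y) and 0.59 (Xist) in WT SCNT against IVF at E14.5, neither past the test. Xist also varied within SCNT groups, at 6.22 and 15.3 FPKM in WT SCNT at E19.5. In IVF replicate 1 Ddx3y was at 0.0292 FPKM at E14.5 and 0.0242 at E19.5. Sex was thus not matched between IVF and SCNT or between the IVF replicates. Comparisons with IVF cannot tell a difference in sex apart from an effect of SCNT.

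In the E9.5 WT SCNT library 94 genes at 5 FPKM or more were under 0.5 in each other library, whereas each other library had 0 or 1 such genes. They made up 1.3% of its FPKM and included Bmp15 (25.7), Tcl1 (16.0), Btg4 (15.2) and Zscan4d (9.64). Gdf9 was at 19.8 FPKM there and up to 0.976 elsewhere, whereas other oocyte transcripts were low in that library: Zp1 at 0.0106, Zp2 at 0.0735, Zp3 at 0.808, H1foo at 0.098, Khdc3 at 0.0987 and Mos at 0. Expression that lasts in WT SCNT placenta is argued against, since the 8 highest genes had a median of 0.0148 FPKM in the later WT SCNT libraries. Reads shared within multi-copy families are argued against as the whole cause, since 32 of the 89 genes searched among these 94 (36%) had no near-identical transcript of another gene. RNA of oocytes or early embryos in that library may be the source: the oocyte list lay at 1.33, between the bounds of 2 and 0.5 set for and against it, with 16 of 18 genes higher but 12 at 1 FPKM or more, the two_cell list at 2.38 with 11 of 11 higher and the inner_cell_mass list at 0.00. With 1 library per group this cannot be told apart from expression in the E9.5 SCNT placenta, which is untested.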
